A study of Caenorhabditis elegans with 2 samples.

How the data were processed

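Gene expression was measured in the nematode Caenorhabditis elegans with 1-colour Agilent arrays, in which cyanine 3-labelled RNA is hybridised to short DNA probes and each spot's brightness is read. Per the labels, the strain was fer-15;fem-1, a temperature-sensitive sterile double mutant often used in studies of ageing, fed the Escherichia coli strain OP50. Total RNA was taken after 6 days and after 12 days of exposure to this food, with 1 array at each time. The labels give L4 as the stage, although harvest came days later, and 15 degrees C as the maintenance temperature. The strain's sterility depends on a raised growth temperature, and neither the temperature during the exposure nor the number of animals per sample is given. Both arrays lie on 1 slide and carry 1 scan time, so neither slide nor scan separates them.

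The deposited scanner files give spot intensity values on a linear scale, per the file headers written by Agilent Feature Extraction 11.5.1.1. Feature Extraction 9.1 is the version listed per the submitters' processing notes, and the difference between these versions was not settled. The intensity used here is the processed signal, which the authors' scanner software had already corrected for background and for trends across the slide, per the file headers, and which had not been scaled between arrays. The authors also deposited a table with 1 ratio per probe, day 12 over day 6. Against its own signals, the log2 of that deposited ratio differed by 1 constant, -0.07, from the log2 ratio of the signals after those under 5 were set to 5. This held within 0.001 for 99.99% of probes, and the lowest deposited ratio was 0.01. For this work, 84 lines of the table were emptied, and probes of those lines carry no name here. A colour legend deposited with the table was not used.

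From the scanner files, log2 of the processed signal minus each array's 75th percentile over non-control probes was computed in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Of 43603 non-control probes, 5 were left out because the scanner software marked their spots as outliers. The spots of the 50 probes with 5 spots each were averaged. No spot was saturated on either array. A probe counted as measured where the software called it well above background, which held for 33754 spots (77.1%) at day 6 and 32574 spots (74.4%) at day 12. Signal over background differs from probe to probe, and with 1 array per time point their number limits the precision.

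Probes were named from the identifiers in the deposited table through a RefSeq gene table of assembly WBcel235, used for names only. A symbol was found for 37200 probes and none for 6319. Of the probes with a symbol, 1888 are annotated to several genes and were left out, which left 35312 probes naming 1 gene and 19906 named genes. A gene's value is the mean over its probes that are well above background on both arrays. Probe positions are those of the deposited table, on build ce4 per the file headers, and no annotation of that build was used here, so the exon or untranslated region under a probe was not analysed here.

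With 1 array per time point there is no statistical test between the ages, no p-value is given, and a difference has no replicate check. Genes are counted by a rule of size, at least 2-fold. The technical error was taken from repeat spots and from probes of the same gene. A gene well above background on 1 array only has a bound: its scaled signal against the higher of its own signal on the other array and the lowest signal among probes well above background there. Each of 60 gene lists with at least 5 measured genes was described by its median log2 difference. That median was ranked among 10000 random lists of the same size, matched on mean signal in 20 bins. A list is called outside the random range where its percentile lies under 2.5 or above 97.5, which describes these 2 arrays and is not a test of age. Classes of genes that share the letters before the hyphen, with at least 10 measured members, were ranked the same way.

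The lists, the main setting, its alternatives other than those named below as later choices, and the rule for named genes were fixed before the data were examined. The rule took the 12 largest differences each way among genes with a class name, with at most 4 of 1 class on each side. Such genes had to be at least 2-fold the same way after a normexp background correction with quantile normalization, with their probes of 1 sign. It also took the 3 largest each way among genes with a sequence name only, the 4 largest bounds each way, up to 4 members with the largest difference in each list discussed, and a preset group of ageing genes. Of the list members that this rule names, 1 is not reported here. Names written with a capital letter after the number, as for cytochrome P450 genes, fall under neither kind and enter through their list.

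The normexp correction came from limma 3.58.1 with an offset of 50. The files hold no mean spot signal, so the median spot signal and the median local background were used in place of the planned columns. Fitted on all spots, as planned, the model gave a baseline of -862 on the day 6 array, where a few spots have a local background of up to 45157.5, against 22.2 on the day 12 array. A second fit without marked spots, 68 on day 6 and 83 on day 12, gave 19.7 and 22.2. It was added after the first fit had been seen, and both are reported. The named-gene rule used the planned fit. With the second fit it would name pals-38 in place of hsp-70 and otherwise the same genes. Other alternatives were quantile normalization, scaling to the median, no scaling, an intensity-dependent loess with a span of 0.3, other summaries of a gene's probes, only the brighter probes, and the deposited ratios. Keeping outlier spots and keeping probes of several genes were chosen after seeing the data.

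The counting and ranking steps were tested on simulated data for the comparison of day 12 with day 6, made from the 15610 measured genes with the repeat-spot error only. Of 50 genes changed 3-fold, 50 passed the 2-fold rule, as did 50 of 50 changed 4-fold, 50 of 50 changed 8-fold and 19 of 50 changed exactly 2-fold. Among 14810 unchanged genes, 0 passed. Of 20 lists of 30 genes shifted by 0.5 on the log2 scale, 20 stood above the random range, and 13 of 200 unshifted lists (6.5%) stood outside it. This simulation holds no variation between animals or cultures. Its error came from 31 repeated probes and was the same for dim and bright signals. Unchanged genes therefore spread far less than in the data, where the log2 difference had an SD of 0.72 over genes and 0.81 in the dimmer part. Passing was easy by construction, so these rates check the steps and do not carry over to the data.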

Results

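Gene expression was compared between fer-15;fem-1 animals after 6 days and after 12 days on E. coli OP50, to follow expression during ageing, as the labels state. There was 1 array at each time and there are no replicates, so the values below describe 2 RNA samples. Differences are day 12 minus day 6 on the log2 scale. A total of 15610 named genes were measured on both arrays, 11246 by 1 probe and 4364 by several.

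Collagens, digestive proteases, detoxification enzymes and targets of the PMK-1 immune pathway were lower at day 12. Pals genes, neuropeptides and sperm genes were higher, as were 4 small heat shock genes. A background model with a failed day 6 fit gave the 3 groups negative medians, but only when scaled to the 75th percentile. Those medians still ranked above matched random lists. In all, 1241 genes (7.95%) were at least 2-fold higher and 869 (5.57%) at least 2-fold lower, and 13500 (86.5%) lay within 2-fold. At a limit of 4-fold, 149 genes were higher and 210 lower, and at 8-fold 29 and 36. Across genes, which are not independent replicates, the 2 arrays correlated with Pearson r = 0.973 and Spearman rho = 0.973.

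The balance of the 2-fold counts rests on the scaling. Higher genes made up 58.8% of them in the main setting, 50.6% with quantile normalization, 48.6% with no scaling, 48.0% with the loess, 44.3% with scaling to the median and 41.3% with the authors' deposited ratios. After normexp without marked spots the share was 48.9% with the 75th percentile and 42.7% with quantile normalization. With normexp fitted on all spots it was 2.49% and 34.7%, and values quoted below from normexp fitted on all spots are those with the 75th percentile. Dim genes carried most of the excess: genes under the median signal counted 1027 higher and 473 lower, and those over it 214 and 396. The log2 difference of a single spot had a technical SD of 0.16 between repeat spots, and probes of the same gene had a pooled SD of 0.19. Of 430 genes with several probes and a 2-fold difference, 429 had probes of 1 sign. Probes of 1 gene can overlap on nearly the same bases, as they do for mrpr-1, rpr-1, hsp-12.6 and F20E11.17. The pooled SD and the shared sign therefore need not show agreement between separate parts of a transcript.

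**Figure D1:**
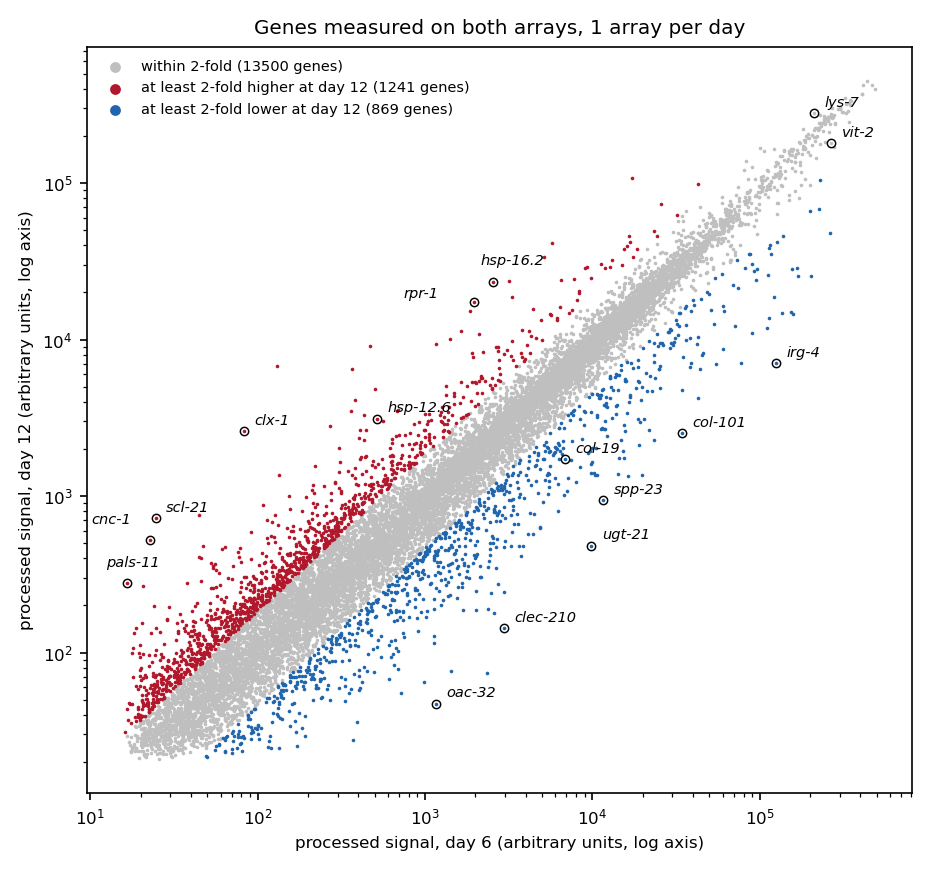
Processed signal at day 6 (x axis) and day 12 (y axis), in arbitrary units on log axes, for each of 15610 genes measured on both arrays, 1 array per day. Red points are the 1241 genes at least 2-fold higher at day 12, blue points the 869 genes at least 2-fold lower, grey points the rest, and circles mark genes named in the text.

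Among genes with a class name, clx-1 was the highest at day 12 relative to day 6, 34.2-fold. Its probe lies on chromosome IV from 7736231 to 7736290 of build ce4. The SCP-like extracellular protein gene scl-21 had a signal of 24.5 at day 6 and 726 at day 12, and cnc-1, which encodes a caenacin antimicrobial peptide, was 24.8-fold higher. Next came pals-11 (18.2-fold), the cathepsin B-like protease gene cpr-2 (11.2-fold) and the lipase-related gene lips-13 (log2 3.45). The RNA component of RNase MRP, mrpr-1, was 10.5-fold higher over 5 probes, with an SD between probes of 0.05 on the log2 scale, and that of RNase P, rpr-1, 9.57-fold over 5 probes with an SD of 0.02. The 5 probes of mrpr-1 lie within 7200274 to 7200348 of chromosome II. Those of rpr-1 lie within 13464126 to 13464195 of chromosome I. Each set overlaps on nearly the same bases, so its small SD is close to a repeat reading of 1 stretch. The small heat shock gene hsp-16.2 was 9.91-fold higher, with a signal of 2561 at day 6 and 23471 at day 12. The other genes of this group were pals-9 (9.86-fold), the F-box gene fbxa-155 (9.46-fold) and the heat-inducible chaperone gene hsp-70 (8.92-fold). Several of these had day 6 signals close to background, as with cnc-1 at 22.7. With normexp fitted on all spots and the 75th percentile, 4 of them turned to negative values: cnc-1 (-0.36), pals-11 (-0.88), pals-9 (-0.50) and fbxa-155 (-0.64). There scl-21 stood at 0.36, lips-13 at 0.83, cpr-2 at 1.64, clx-1 at 1.78 and mrpr-1 at 1.90. Dim genes were also smaller with normexp without marked spots and the 75th percentile, where scl-21 stood at 3.42, cnc-1 at 2.76 and pals-11 at 2.29. Among genes with only a sequence name, ZK355.3 was 56.2-fold higher, F20E11.17 21.1-fold over 5 probes and W02D7.11 stood at 4.25 on the log2 scale.

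The lowest class-named genes were the acyltransferase-like oac-32 (22.7-fold lower), the C-type lectin gene clec-210 (19.1-fold) and the UDP-glucuronosyltransferase gene ugt-21 (18.9-fold over 2 probes). The folate transporter gene folt-2 was 17.3-fold lower. The infection response gene irg-4 (log2 -4.04) was lower from a much brighter signal, 125313 at day 6 and 7051 at day 12. Its probe lies on chromosome IV from 12438079 to 12438138 of build ce4. The astacin protease gene nas-3 was 14.1-fold lower over 6 probes, and the collagen gene col-101 (log2 -3.66), the glucosylceramidase gene gba-2 (-3.60) and irg-6 (-3.53) followed. The saposin-like gene spp-23 (11.4-fold over 5 probes), col-179 (11.3-fold over 9 probes) and col-141 (10.1-fold) came next. The lowest genes with a sequence name only were Y48E1B.8 (29.4-fold), D1086.3 (13.5-fold) and F21C10.9 (13.4-fold).

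A further 941 genes were well above background on 1 array only, 642 at day 6 and 299 at day 12. For 205 of the day 12 genes and 105 of the day 6 genes the bound was at least 2-fold. The gene scl-11 was at least 28.6-fold higher at day 12, and the transcription factor gene grh-1 at least 12.5-fold, both not well above background at day 6. The same held for nspb-12 (log2 of at least 3.52) and grl-23 (at least 9.26-fold). In the other direction, cror-2 (at least 5.76-fold lower), folt-3 (5.74-fold), srx-10 (5.38-fold) and str-131 (5.21-fold) were not well above background at day 12, each figure being a lower bound.

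Of 60 gene lists, 29 lay outside the random range, 9 above it and 20 below it. About 3 would by chance if the lists were independent and their genes varied separately. Some lists share genes, and random lists do not keep genes that vary together, so the excess over 3 is not a test. Immune and digestive genes made up the lowest 3 lists. Among 15 measured lysozyme genes, which encode enzymes that break bacterial cell walls, 7 were at least 2-fold lower and 4 higher, with a median of -0.99 (random lists -0.20 to 0.18). The members with the largest differences went both ways: ilys-3 (2.98), ilys-6 (2.67) and lys-3 (1.96) were higher and lys-2 (-1.97) lower. With the mean in place of the median this list lay inside the random range, at -0.10. Lysosomal proteases had a median of -0.93 (random lists -0.13 to 0.13), with 12 of 25 genes at least 2-fold lower and 2 higher. The aspartyl proteases asp-8 (-3.21) and asp-13 (-2.58) were among the lower genes, and cpr-2 (3.48) and asp-9 (3.03) were the higher pair. Targets of the PMK-1 pathway, the p38 kinase arm of nematode immunity, had a median of -0.91 (random lists -0.19 to 0.19), with 10 of 21 genes at least 2-fold lower and 1 higher. The genes irg-4 (-4.04), irg-6 (-3.53), C17H12.6 (-2.57) and clec-67 (-2.36) led this list. Saposin-like genes, a further immune list, had a median of -0.56 (random lists -0.13 to 0.16), with spp-23 (-3.51), spp-17 (-3.09) and spp-4 (-2.46) lower and spp-31 (1.89) higher.

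Intestinal marker genes had a median of -0.59 (random lists -0.20 to 0.16). Of 22 measured, 5 were at least 2-fold lower and 1 higher, with the acid phosphatase gene pho-1 at -2.83, the peptide transporter gene pept-1 at -2.03, pgp-1 at -1.84 and vha-6 at -1.24. C-type lectins, a large family with many immune members, were mixed: 35 of 156 were at least 2-fold lower and 22 higher. Their median of -0.01 lay under that of matched random lists (0.02 to 0.23). It was 0.04 after normexp without marked spots with the 75th percentile, though negative there with quantile normalization, and 0.16 with no filter on dim probes. The list lay inside the random range with no filter and against random lists matched on size only. The lectin genes clec-210 (-4.26) and clec-53 (-3.17) were lower, and clec-17 (3.05) and clec-121 (3.03) higher.

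Detoxification enzymes were lower at day 12 in 3 families. UDP-glucuronosyltransferases, which attach sugars to foreign compounds, had a median of -0.59 (random lists -0.11 to 0.18), with 24 of 63 genes at least 2-fold lower and 6 higher. The largest differences were those of ugt-21 (-4.24), ugt-53 (-2.91) and ugt-37 (-2.89) against ugt-35 (2.84). Glutathione S-transferases had a median of -0.40 (random lists -0.12 to 0.19), with 12 of 43 lower, among them gst-21 (-2.85), gst-35 (-2.37), gst-26 (-2.23) and gst-10 (-2.21), and 1 higher. For cytochrome P450 genes the median was -0.23 (random lists -0.09 to 0.20), and 13 of 61 were lower and 6 higher. The genes cyp-35A5 (-3.64), cyp-29A3 (-2.86) and cyp-35C1 (-2.85) were lower and cyp-13B1 (3.38) was higher.

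Cuticle collagens, the structural proteins of the body surface, had a median of -0.42 (random lists -0.03 to 0.17). Of 121 measured, 48 were at least 2-fold lower and 12 higher. The genes col-101 (-3.66), col-179 (-3.49), col-141 (-3.33) and col-181 (-3.33) had the largest differences, and the adult collagen gene col-19 stood at -1.88 over 2 probes. Other cuticle genes had a median of -0.20 (random lists -0.05 to 0.25) but went both ways, 12 of 74 at least 2-fold higher and 7 lower. Its genes sqt-1 (2.93) and rol-6 (2.33) were higher from dim day 6 signals, while grd-14 (-2.47) and dpy-3 (-2.35) were lower. With the mean in place of the median, or normexp fitted on all spots, this second list lay inside the random range. Body wall muscle genes had a median of -0.18 (random lists -0.11 to 0.14), and 9 of 44 were at least 2-fold lower, with 0 higher. The troponin gene tnt-2 (-2.33 over 7 probes), the myosin light chain gene mlc-1 (-1.87 over 5), alp-1 (-1.51) and the troponin gene pat-10 (-1.40) led these.

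Lipid genes were lower in several lists. Vitellogenins, the yolk proteins, were lower in 6 of 6 genes, with a median of -0.55 (random lists -0.27 to 0.17), though only vit-1, at a signal of 112078 on day 6 and 25913 on day 12, reached 2-fold. The gene vit-3 stood at -0.99, vit-6 at -0.65, vit-2 at -0.46 and vit-5 at -0.16, or above 0 with normexp fitted on all spots. Beta oxidation and lipase genes had a median of -0.22 (random lists -0.08 to 0.11), with 14 of 71 at least 2-fold lower and 5 higher. Among them were acox-1.3 (-2.17), lipl-3 (-2.07), hacd-1 (-2.02) and ech-7 (-1.96). Fatty acid desaturases and elongases had a median of -0.21 (random lists -0.15 to 0.16), with the elongase genes elo-6 (-2.68), elo-5 (-2.16), elo-2 (-1.94) and elo-9 (-1.71) lower. Lipid binding genes had a median of -0.32 (random lists -0.17 to 0.13), with lbp-8 (-2.51), far-3 (-1.63) and lbp-7 (-1.61) lower and far-7 (2.68) higher. Tricarboxylic acid cycle genes had a median of -0.18 (random lists -0.14 to 0.12), which became 0.13 with normexp fitted on all spots, and the list lay inside the random range in 6 of 16 alternatives. Only idhg-2 (-1.37) of its 21 genes reached 2-fold.

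Small heat shock genes, whose products bind unfolded proteins, had a median of 0.34 (random lists -0.28 to 0.24). Of 10 measured, 4 were at least 2-fold higher and 0 lower: hsp-16.2 (3.31), hsp-16.41 (3.02 over 2 probes), hsp-12.6 (2.71 over 6 probes) and hsp-12.3 (2.05 over 6 probes). Of the other 6 genes, 4 lay below 0. Cytosolic chaperones as a group lay inside the random range with a median of 0.08, and hsp-70 (3.16) was the 1 gene of 44 beyond 2-fold. Genes activated by DAF-16, the transcription factor under insulin signalling, had a median of 0.21 (random lists -0.14 to 0.11) with 5 of 27 higher and 4 lower. The genes hsp-16.2 and hsp-12.6 are also members of this list, which further held dct-18 (-1.82) and the ferritin gene ftn-1 (1.49). Genes repressed by DAF-16 had a median of -0.46 (random lists -0.16 to 0.19), with ugt-16 (-2.83), dod-24 (-1.26) and col-142 at least 2-fold lower and mtl-2 at -0.84. Both heat shock and DAF-16 activated lists lay inside the range of random lists not matched on signal.

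The preset genes for signalling and transcription were within 2-fold in the main setting. The insulin receptor gene daf-2 stood at 0.02 with an SD of 0.12 between 7 probes, daf-16 at 0.19 (SD 0.13, 5 probes), age-1 at -0.12, skn-1 at 0.17 and pmk-1 at -0.23. The heat shock factor gene hsf-1 stood at 0.40, hlh-30 at 0.50 with an SD of 0.32 between 2 probes, and elt-2 at -0.35. The superoxide dismutase gene sod-3 stood at -0.60, the lysozyme gene lys-7 at 0.53 and the metallothionein gene mtl-1 at 1.07, more than 2-fold higher. Of the 2 genes mutated in the strain, fem-1 stood at 0.23 (SD 0.14, 7 probes), and fer-15 had no probe naming 1 gene. With normexp fitted on all spots the sign of 5 of these turned: daf-2 (-0.81), daf-16 (-0.09), skn-1 (-1.02), hlh-30 (-1.31) and fem-1 (-1.06). Other scalings turned daf-2 too, as its value is smaller than the shift between them, and the deposited ratios turned skn-1.

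Infection response genes, a list that shares irg genes with the PMK-1 targets, had a median of 0.38 (random lists -0.08 to 0.17), but their median was -0.19 among brighter probes, below the random range, and -0.77 with normexp fitted on all spots, inside it. Of 60 measured, 22 were at least 2-fold higher and 8 lower. The higher ones were mostly pals genes, a family induced by intracellular pathogens: 18 of 30 pals genes were at least 2-fold higher and 1 lower. Their class median was 1.33 (random lists -0.13 to 0.41), -0.98 with normexp fitted on all spots, the one setting of 8 scaling and background settings that turned it, and there it still stood above its matched random lists. The pals median was smaller, 0.88 and 0.76, after normexp without marked spots with the 75th percentile and with quantile normalization, and 0.45 with normexp fitted on all spots and quantile normalization, each above its matched random lists. Among the 17 irg and dod genes, which were much brighter, 0 were higher and 5 lower, with a median of -0.27. The genes pals-11 (4.18), irg-4 (-4.04), irg-6 (-3.53) and pals-9 (3.30) had the largest differences. Antimicrobial peptide genes had a median of 0.26 (random lists -0.09 to 0.16), which was -0.59 with normexp fitted on all spots. The list lay inside the random range in that setting and among brighter probes. Of these, 11 of 52 were higher and 5 lower, with cnc-1 (4.63), cnc-6 (1.79) and cnc-4 (1.76) higher and nlp-26 (-2.18) lower.

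Neuropeptide genes were higher as a group, with a median of 0.46 (random lists -0.13 to 0.16), except with normexp fitted on all spots, which gave -0.20. The difference was small and shared: 49 of 54 genes lay above 0, while only flp-10 (1.02 over 3 probes) reached 2-fold. The genes flp-5 (0.89), nlp-8 (0.87) and nlp-2 (0.86) followed. The list holds only part of the nlp genes. Over all 71 measured nlp genes the median was 0.16, at the upper edge of random lists (-0.10 to 0.16). Of these 71, 23 lay below 0, 5 were at least 2-fold higher and 4 lower. The flp class had a median of 0.48, with 27 of 30 genes above 0. Insulin-like peptide genes had a median of 0.30 (random lists -0.13 to 0.28), which was -0.80 with normexp fitted on all spots, and the list lay inside the random range in 9 of 16 alternatives, so its place is not settled. Of 36 measured, 7 were at least 2-fold higher, including ins-11 (2.69), ins-4 (2.52), ins-10 (2.21) and ins-20 (1.84), and 1 was lower. Chemoreceptors, mostly dim, had a median of 0.16 that lay under the range of matched lists (0.18 to 0.37). It was -0.09 with the loess, -0.02 with the authors' deposited ratios, -2.61 with normexp fitted on all spots and 0.37 among brighter probes. The chemoreceptor list lay inside its range with normexp fitted on all spots. It stood above the range among brighter probes and against random lists matched on size only. The receptor genes sri-39 (2.81), str-114 (2.61) and srg-47 (2.61) were higher and srh-211 (-2.40) lower.

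Sperm genes were higher as a group, with a median of 0.63 (random lists -0.06 to 0.17), except with normexp fitted on all spots, which gave -0.34. Of 81 measured, 75 lay above 0, 13 were at least 2-fold higher and 0 lower. Among them were spe-57 (1.40), smz-1 (1.29) and the phosphatase gene gsp-3 (1.31). Even with normexp fitted on all spots, sperm and neuropeptide genes ranked above their matched random lists. The sperm classes parted in that setting: the spe class stood at -1.55 and the ssp class at -0.81. The msp class, made of near copies, stayed at 0.46 or above in all 8 scaling and background settings. How far the msp genes carry the rank of the sperm list in that setting was not tested. Germline and oocyte genes as a group lay inside the random range with a median of 0.02, and 54 of 54 genes lay within 2-fold.

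Cytosolic ribosomal protein genes had a median of 0.13 (random lists -0.08 to 0.02), with 69 of 77 above 0 and all within 2-fold, but -0.03 with scaling to the median and -0.05 with the authors' deposited ratios. Mitochondrial ribosomal protein genes had a median of 0.09 (random lists -0.06 to 0.07), which was -0.06 with scaling to the median, -0.02 with no scaling and -0.09 with the deposited ratios. Both lists kept their place above the matched random lists under those scalings, which shift nearly all genes alike and so can hardly move a rank. Neither stood out from random lists matched on size only. The mitochondrial list also lay inside the random range with normexp fitted on all spots and with the mean in place of the median. F-box and MATH-BTB genes had a median of -0.06 (random lists 0.00 to 0.12), with 32 of 363 higher and 25 lower. They lay inside the range among brighter probes and with normexp fitted on all spots.

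The other 31 lists lay inside the random range. Among them were the insulin pathway (median 0.02), autophagy (0.09), proteasome subunits (0.02), oxidative phosphorylation (-0.08), antioxidant enzymes (-0.07) and longevity regulators (0.08). Pharynx (0.20), neuron synapse (0.15), cilia (0.28), hypodermis (-0.19) and histone genes (0.04) also lay inside. Oxidative phosphorylation genes were all within 2-fold, as were the 33 proteasome and 28 autophagy genes.

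**Figure D2:**
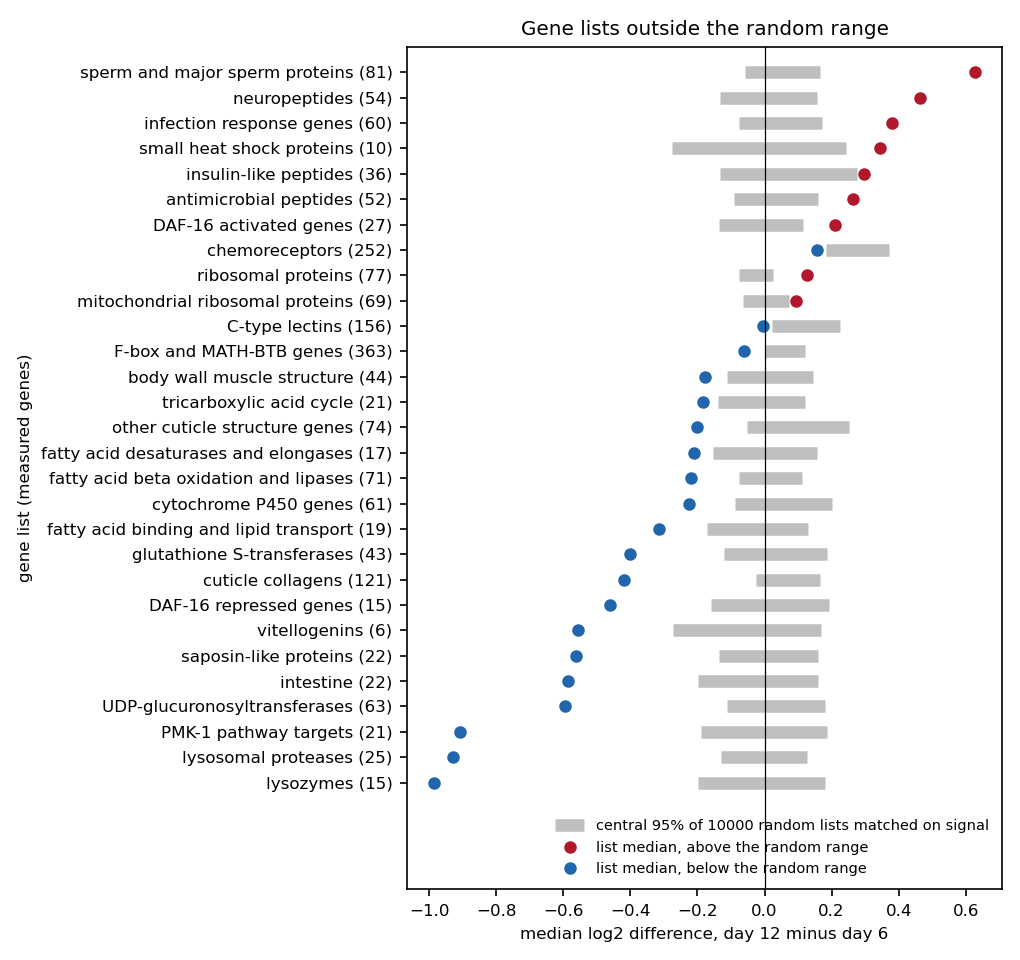
Median log2 difference, day 12 minus day 6 (x axis), of the 29 gene lists outside the random range, with the number of measured genes after each list name. Grey bars span the central 95% of 10000 random lists matched on signal, red points are medians above that range and blue points medians below it, from -0.99 for lysozymes to 0.63 for sperm genes. With normexp fitted on all spots and the 75th percentile the medians of sperm genes, neuropeptides, infection response genes, insulin-like peptides, antimicrobial peptides, chemoreceptors and the tricarboxylic acid cycle change sign. Scaling turns the ribosomal lists and chemoreceptors. C-type lectins are turned by normexp without marked spots with the 75th percentile, but not with quantile normalization, and by no filter on dim probes.

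**Figure D3:**
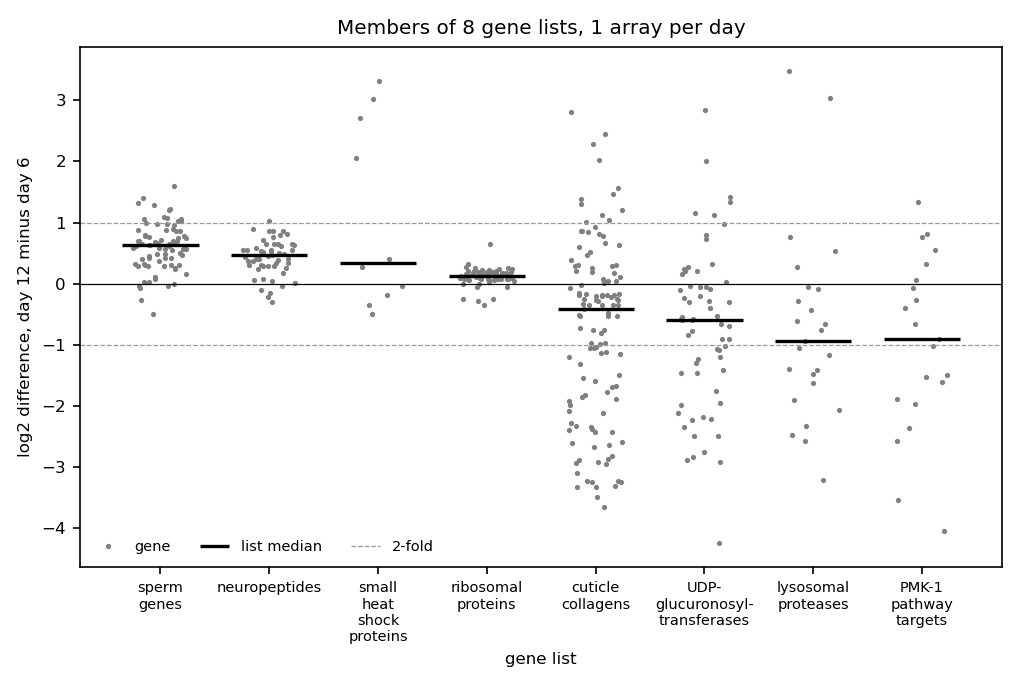
Log2 difference, day 12 minus day 6 (y axis), of each measured gene in 8 lists (x axis), with 1 point per gene, a black line at the list median and dashed lines at 2-fold. Sperm and neuropeptide genes lie close around 0.63 and 0.46, or -0.34 and -0.20 with normexp fitted on all spots, ribosomal protein genes around 0.13, or -0.03 with scaling to the median, and collagens spread widely around -0.42.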

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

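The counts in this part were chosen after the data were seen, and no test was run on them. Probes outside the comparison of named genes also carried signal. Of 6319 probes with no gene name, 3101 were well above background on both arrays, while 0 of 153 negative control spots were. Among these unnamed probes, 131 were at least 2-fold higher at day 12 and 71 at least 2-fold lower. Probes annotated to several genes gave 1500 well above background on both arrays, of which 177 were higher and 105 lower by the same limit.

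In the authors' deposited table, 4 probes stand at the lowest ratio, 0.01. They belong to Y60A9.3, mlst-8, vps-4 and Y54F10AL.1, and the scanner software marked all 4 spots as outliers on the day 6 array. Their day 6 signals were 184616, 370888, 158889 and 294668, and the spots lie together in rows 390 to 396 and columns 17 to 18 of the array. For vps-4 and its 3 companions these values were left out of the comparison.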

How the results depend on the processing

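The fits without marked spots, the setting with outlier spots kept and that with probes of several genes kept were chosen after seeing the data. No paired analysis was possible because each time point has 1 array and nothing was tested. Leaving out saturated spots was void, since 0 spots were saturated. Scaling by 1 factor cannot move a list's rank. The median of all genes was 0.04 in the main setting, -0.11 with scaling to the median, -0.14 with the authors' deposited ratios and -0.66 with normexp fitted on all spots and the 75th percentile, and differences are best read relative to it.

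Higher genes numbered 1241 in the main setting. Normexp on all spots gave 168 with the 75th percentile and 226 with quantile normalization, and without marked spots 580 and 488. The brighter probes alone gave 245, limits of 1.5-fold and 3-fold 2689 and 326, and probes in place of genes 2246. Lower genes numbered 869, against 6581 and 426 with normexp on all spots, 445 among brighter probes, 1947 and 367 at the other limits, and 1565 probes. Of the 168 and 226 genes, 131 and 222 were also higher in the main setting. Higher genes made up 58.8% of the calls in the main setting and 2.49% and 34.7% with normexp on all spots, 48.9% and 42.7% without marked spots, 50.6% with quantile normalization, 44.3% with median scaling, 48.6% unscaled, 48.0% with the loess, 41.3% with the deposited ratios and 35.5% among brighter probes. The baseline of -862 on day 6 goes with the fit on all spots, but the fit without marked spots also gave fewer higher genes. By construction, the offset of 50 added to every normexp value shrinks the ratios of dim genes. The baseline of -862 also raises all day 6 signals, which lowers the differences of dim genes after scaling to the 75th percentile. Such moves of dim genes would arise whatever their true difference, and the share of each step was not tested.

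The correlation of 0.973 became 0.952 and 0.979 with normexp on all spots, 0.977 and 0.977 without marked spots, 0.981 with no filter, 0.974 with the brightest probe and 0.943 among brighter probes. Genes on 1 array only numbered 941, and 310 with a bound of at least 2-fold.

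Of the 29 lists outside the random range, 16 kept that place in all 16 alternatives and 13 lost it in some, and 10 changed sign in some. Another 10 lists stood outside in some alternative only. With normexp on all spots and the 75th percentile the changed signs were antimicrobial peptides -0.59, infection response -0.77, tricarboxylic acid cycle 0.13, neuropeptides -0.20, insulin-like peptides -0.80, chemoreceptors -2.61 and sperm -0.34, and for genes cnc-1 -0.36, pals-11 -0.88, pals-9 -0.50 and fbxa-155 -0.64. Ribosomal proteins turned to -0.0302 with median scaling and -0.0542 with the deposited ratios, and mitochondrial ones to -0.0627, to -0.0867 and, unscaled, to -0.0200. Chemoreceptors turned to -0.0949 with the loess and -0.0222 with the deposited ratios, and stood above their range among brighter probes (0.37). C-type lectins turned to 0.16 with no filter and 0.0441 with normexp without marked spots and the 75th percentile, but did not turn with quantile normalization. Infection response genes turned to -0.19 among brighter probes and stood below their range there. Apart from what the offset and baseline of normexp do to dim genes by construction, the cause was not tested beyond these settings. Of 628 values of 46 named genes, 502 stayed within the pooled SD between probes. The shift of all genes by scaling to the median, no scaling or the deposited ratios is smaller than that SD. Those alternatives could therefore hardly move a value beyond it. Besides the 4 genes above, preset genes with small values changed sign, 10 of 46 genes in all. Signals close to background limit the dim genes most.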

Other observations

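The tests of the pathogen response genes, of the sperm list without near copies and of other tissues against intestinal RNA were chosen after the result was seen, as was the look at RNA types. Ranked by class name, 14 of 152 gene classes lay above the random range and 25 below it. Small secreted nspg and nspc genes, 13 of each, had medians of -0.94 and -0.82, with 6 of each at least 2-fold lower and 0 higher. Carboxylesterase genes (cest) had a median of -0.62 with 6 of 29 lower and 0 higher, and the heme-responsive hrg genes -0.56 with 5 of 13 lower and 0 higher. The fbxb branch of the F-box family had a median of -0.35 over 96 genes, with 9 at least 2-fold lower and 1 higher. Subunits of the vacuolar proton pump (vha) had a median of -0.24 with 1 of 20 at least 2-fold lower and 0 higher. SCP-like scl genes had a median of 0.61 with 7 of 18 at least 2-fold higher and 2 lower, or -1.82 with normexp fitted on all spots. With that setting, the scl, cest and fbxb classes lay inside the random range.

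Several non-coding genes were higher at day 12. Besides rpr-1 and mrpr-1, the genes tts-2 (2.52-fold), C30E1.9 (2.67-fold) and F09E10.10 (signal 82.3 at day 6 and 304 at day 12) of the non-coding type and F11A5.14 (6.05-fold), an snRNA gene, were at least 2-fold higher at day 12. Of 31 measured genes of the ncRNA type, 5 were at least 2-fold higher and 0 lower, and their median of 0.21 lay inside the random range (-0.12 to 0.25).

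The pals genes were higher at day 12, with a class median of 1.33, and the loess left 1.17, above matched lists (-0.26 to 0.28). The loess removes only a trend shared by genes of like signal, on which the lists were already matched, so the rank could hardly change. The small fall in the median argues only against such a trend as the whole cause. With normexp the pals median ranked above matched lists too, at 0.88 without marked spots and -0.98 on all spots. The normexp offset, and the day 6 baseline in the fit on all spots, lower such dim genes by construction. Dim signals may account for part of the median's size, but these falls cannot measure how much. As for sequence shared between pals probes, 0 of the 18 higher genes had a probe that shared a run of 20 bases with the probe of another pals gene. Probes annotated to several genes had been left out, and probes from different parts of the transcripts need not share bases. Matches to the rest of their transcripts were not tested, so this cannot decide whether the probes bind transcripts of other pals genes. A wider intracellular pathogen response may be part of the pals difference. In the main setting, the only one used for them, 22 other genes of that response had a median of 1.21 (random lists -0.17 to 0.42). Of these, 12 were at least 2-fold higher, eol-1 (2.48) and chil-18 (2.84) among them, and 1 lower, sdz-6 (-3.06). Day 6 signals of the 12 ran from 16.7 for T08E11.1 to 686 for eol-1. How far dim signals add to this median was not tested. An infection of 1 culture and an effect of age stay open, as untested.

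Sperm genes were higher at day 12 in a strain whose sterility depends on growth temperature. The loess left their median at 0.58, against 0.63 in the main setting, above the range of matched lists (-0.12 to 0.11). As those lists were already matched on signal, this argues only against a trend shared by genes of like signal as the whole cause. The list without the near copies of the msp, nspd, ssp and ssq classes had a median of 0.78 over 39 genes in the main setting, the only one used for it. Sequence shared between copies is therefore not the whole cause there either. A candidate explanation is more sperm-bearing animals among those harvested at day 12. The median was 0.56 among the 41 brighter genes of the list (random lists -0.14 to 0.11) and 0.75 among the 40 dimmer ones. Such a cause would give this, but with 75 of 81 genes above 0 the split could hardly turn out otherwise. It does not measure the number of such animals and cannot decide. More sperm transcripts per animal would give the same values, and age stays open, as untested.

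Immune and digestive genes of the intestine were lower at day 12, with a median of -0.70 over the 81 genes of 4 lists, 33 of them at least 2-fold lower and 8 higher. The loess, which removes a trend shared by genes of like signal, gave -0.74 (random lists -0.09 to 0.07). The random lists were already matched on signal, so the rank could hardly change. As the median barely moved, a compression shared by all bright genes is argued against, and no other kind was tested. A lower share of intestinal RNA would raise the markers of all other tissues alike, whereas body wall muscle genes stood at -0.18 and neuropeptides at 0.46, outside their random ranges on opposite sides. Pharynx (0.20), neuron (0.15) and germline genes (0.02) lay above 0 and inside their ranges. Intestinal marker genes themselves had a median of -0.59 (random lists -0.20 to 0.16). A separate fall of muscle genes would leave a lower intestinal share possible. The muscle values therefore cannot decide how much such a share may add to the difference. An effect of age and a difference between the 2 cultures stay open, as untested.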
